A study of Tradescantia spathacea with 6 samples.

How the data were processed

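RNA-seq was performed on leaves of Tradescantia spathacea, a monocot ornamental with purple-coloured leaf undersides, after 2 years of growth in full sunlight (100%) or at 30% of full sunlight. There were 3 libraries per light condition. Per the labels' protocols, RNA was isolated with a Trizol-based extractor kit and libraries were made with the NEBNext Ultra RNA kit. The labels name no plant, harvest day or sequencing batch, so p-values measure only the spread between these samples, which may be technical.

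The deposited table held 91987 assembled genes, each with an estimated count and an FPKM value in every library. Its identifiers have the form that the Trinity assembler gives. RSEM, a program that divides reads among transcripts, is named in the submitters' processing notes without a version. The aligner, the read filters and the assembly settings are not given in the sources used here. The estimated counts were deposited by the authors as whole numbers. In each library, 24 to 39 genes had a count of 0 beside an FPKM above 0, as rounding of fractional estimates would give. The deposited FPKM values were scaled by the authors to effective gene length and library size. The table gives no gene symbol, description or sequence, and no reference was used here. Therefore the 35 gene lists written before the data were examined, covering pathways, cell types and other organisms, matched 0 identifiers, and no list was tested. Whether an entry is a whole gene, a fragment, a near-identical copy or an antisense transcript is likewise not known from the table, and reads shared between such entries can be split among them.

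Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr at its defaults, which left 40084 genes holding 99.2% of all counts. Libraries were scaled by TMM (trimmed mean of M values). A quasi-likelihood F test compared full sunlight with low light, two-sided, with all 6 libraries and no other term in the model. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Log2 fold changes are full sunlight relative to low light, and their standard errors (SE) were taken from the F statistic. CPM values (edgeR's cpm function) are scaled by the TMM factors. Values of 1 library measure compared between groups of 3 were tested by exact two-sided permutation, whose smallest possible p is 0.1.

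Total counts ranged from 14748349 to 15958899 per library, and the median tested gene had 76 to 90 counts per library. A count of 0 allows a level of up to 3 counts, which is 0.184 to 0.216 CPM in these libraries, for counting error only. Within a group, the chi-square statistic of 2 libraries' counts per degree of freedom was at least 8.60, where sampling noise alone gives about 1. No 2 libraries thus agreed within sampling noise, as one library deposited more than once would, and each was counted as 1 sample. This does not tell whether they came from separate plants.

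The genes named were fixed by rule before the data were examined. For a table without names, these were the 2 called genes with the largest increase and the 2 with the largest decrease. They also needed a mean of at least 10 CPM and all 3 libraries of one condition above all 3 of the other. Of the tested genes, 3576 met these criteria. The alternatives were also written beforehand: other scalings, DESeq2 1.42.0, limma 3.58.1 with voom, other count filters and thresholds, the replicate number as a block, leaving out each library, and limma on the logarithm of FPKM. The 100 most abundant genes were ranked by their mean share of counts over the 6 libraries, a grouping chosen after the data were seen.

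The scripts were tested on simulated data with the real genes, library sizes and dispersions for the comparison of full sunlight with low light. Of 40084 simulated genes, 100 were changed 2-fold and 100 changed 4-fold, all drawn from genes above a minimum mean CPM. This is a far smaller share than the 15.4% of genes called in the data. The Benjamini-Hochberg threshold depends on that share, so the recovery below may differ from that in the data. The edgeR test recovered 39% of the 2-fold and 85% of the 4-fold changes, and 11.4% of its 140 calls were false. DESeq2 recovered 45% and 87%, with 23.3% of 172 calls false, and limma-voom recovered 37% and 85%, with 8.96% of 134 calls false.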

Results

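Leaf transcripts of Tradescantia spathacea were measured in 3 libraries from plants kept in full sunlight and 3 from plants kept at 30% of it, both for 2 years. By its title, the study asked how leaves balance anthocyanin-based protection from strong light against photosynthetic capacity. Total counts were 14748349, 15958899 and 14961495 in full sunlight replicates 1 to 3 and 15084473, 14961576 and 14971992 in low light replicates 1 to 3. The totals of both conditions overlapped (exact two-sided permutation test, p = 1). The table pairs its assembled genes with no gene names. Genes of anthocyanin synthesis, photosynthesis or any other pathway are therefore not reported by name, and the groups described are those that the counts define.

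The first comparison concerned how the transcripts of a leaf were divided among genes. The most abundant leaf transcripts took a smaller part of the library in full sunlight. The 100 most abundant genes held 13.9% ± 2.32 of counts (SD, n = 3) in full sunlight and 19.7% ± 1.33 in low light. The 10 most abundant held 4.29% ± 1.57 and 7.47% ± 0.889, and the 1000 most abundant held 36.7% ± 2.23 and 42.2% ± 1.11. All 3 full sunlight libraries lay below all 3 low light libraries in each of these shares. The single most abundant gene held 0.627%, 1.48% and 0.998% of counts in full sunlight replicates 1 to 3. It held 1.99%, 2.06% and 1.35% in low light replicates 1 to 3, so its ranges overlapped.

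More assembled genes were detected in full sunlight. At least 1 count was found for 72190 ± 1295 genes (SD, n = 3) in full sunlight and 67568 ± 398 in low light, a difference of 4623 genes. At least 5 counts were found for 50459 ± 816 and 47814 ± 232 genes. When every library was thinned to the 14748349 counts of the shallowest, the difference at 1 count was 4495 genes. Thinning evens out depth but not composition: abundant genes still took more of the low light libraries. Before thinning, the median tested gene had 84 to 90 counts in full sunlight libraries and 76 to 79 in low light. The number of genes detected is therefore not independent of the shares above. At full depth, the differences in shares and in genes detected each had an exact permutation p of 0.1. This is the smallest that 3 against 3 libraries can give. The share of the single most abundant gene was the exception, with an exact permutation p of 0.2. Over the 8 library measures compared, the smallest Benjamini-Hochberg adjusted value was 0.133, so none passed 0.05.

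**Figure D1:**
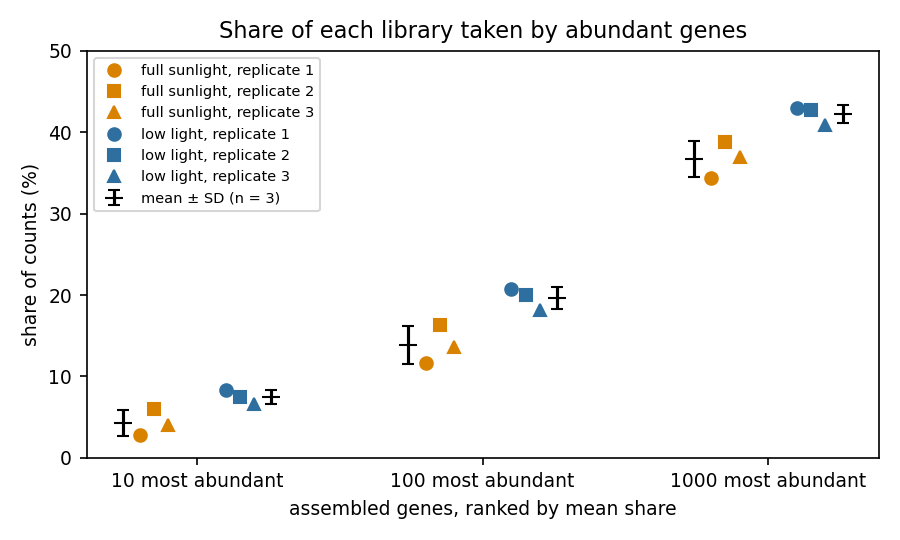
Share of each library's counts (%, y axis) in the 10, 100 and 1000 most abundant assembled genes (x axis), with 1 point per library and black bars for the mean ± SD of the 3 libraries of a condition. The sets are nested. For the 100 most abundant genes the full sunlight libraries lie between 11.7% and 16.3%, all below the low light libraries at 18.2% to 20.8%.

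The second comparison asked which genes differed between light conditions. Of 40084 genes tested, 6173 (15.4%) differed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 2714 were higher and 3459 lower in full sunlight. The median log2 fold change was 0.99 among the genes called higher and -1.11 among those called lower. Changes of at least 2-fold were seen in 1319 genes called higher and 2000 called lower. In 14360 of the tested genes (35.8%) all 3 libraries of one condition lay above all 3 of the other, where chance gives 10% on average over divisions of the libraries. Genes vary together, so in a single division the share can lie far from 10% by chance. Such separation held for 6118 of the 6173 called genes, which is no separate support, since calls and separation rest on the same counts.

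The balance of directions depended on the scaling. With library size in place of TMM, the median log2 fold change of all tested genes moved from 0.02 to 0.20, and the calls became 5187 higher and 2458 lower. With limma on log2(FPKM + 1), which also changes the unit, the filter and the test, 583 genes were higher and 311 lower. The number of calls also depended on single libraries. It was 3792 without full sunlight replicate 1, 2374 without replicate 3, 2711 without low light replicate 1 and 2544 without low light replicate 3. Without full sunlight replicate 2 it was 8976, with 5209 genes lower.

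The full sunlight libraries differed among themselves, and replicate 2 lay nearest to low light. The first principal component of log2 CPM, with 53.8% of the variance, separated the light conditions. It placed full sunlight replicates 1 and 3 at -102 and -80.5, replicate 2 at -28.9 and the low light libraries at 57.4 to 78.6. Across genes, which are not independent replicates, the Pearson correlation of log2 CPM was 0.948 between full sunlight replicates 1 and 2, 0.970 between replicates 1 and 3 and 0.962 between replicates 2 and 3. Replicate 2 correlated with the low light libraries at 0.940 to 0.950, and replicate 1 at 0.905 to 0.915. The low light libraries correlated with one another at 0.964 to 0.966. Over genes with a mean of at least 10 CPM, the SD of the log2 ratio of a library to the mean of the other 2 of its condition was 0.381 for full sunlight replicate 1, 0.41 for replicate 2 and 0.265 for replicate 3. It was 0.252 to 0.29 for the low light libraries.

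The most abundant genes fell more often than they rose. Among the 155 tested genes with a mean of at least 500 CPM, 56 (36.1%) were lower and 8 (5.16%) higher in full sunlight, with a median log2 fold change of -0.53. From 200 to 500 CPM, 109 of 457 genes (23.9%) were lower and 36 (7.88%) higher. From 50 to 200 CPM, 603 of 3645 genes (16.5%) were lower and 394 (10.8%) higher. From 10 to 50 CPM the counts were 1330 lower and 1072 higher of 11242, and from 2 to 10 CPM they were 988 and 817 of 12803. Below 2 CPM, 373 genes were lower and 387 higher of 11782. With library size in place of TMM, lower calls still outnumbered higher ones at 500 CPM or more (46 to 17) and were nearly level with them from 200 to 500 CPM (88 to 82). The balance turned from 50 to 200 CPM (410 lower, 769 higher), from 10 to 50 CPM (864 and 2142), from 2 to 10 CPM (741 and 1500), and below 2 CPM it was 309 lower and 677 higher. Fewer counts may limit the calls in the lower classes, which was not tested. With TMM, the ratio of lower to higher calls was larger at 200 CPM or more (165 to 44) than below (3294 to 2670), with an odds ratio of 3.04 (95% interval 2.16 to 4.36, Fisher's exact test, two-sided p = 2.5e-12). That test treats genes as independent, which they are not.

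**Figure D2:**
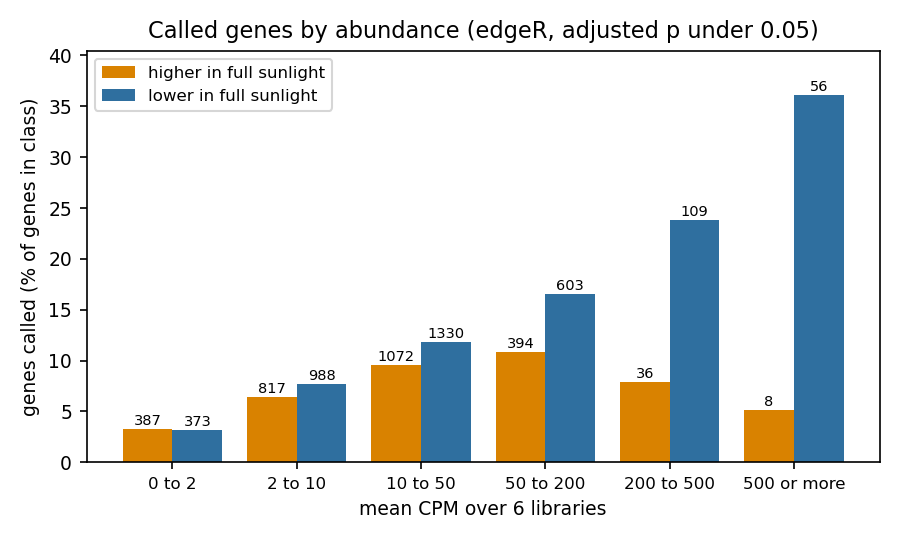
Percentage of tested genes called higher (orange) or lower (blue) in full sunlight (y axis) by mean CPM over the 6 libraries (x axis), with the number of called genes above each bar. With TMM scaling, the lower calls reach 36.1% of genes at 500 CPM or more, and the higher calls 5.16%; with library size alone the higher calls outnumber the lower ones in every class under 200 CPM.

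Of the 100 most abundant genes, 42 were called lower and 6 higher in full sunlight by edgeR, and 21 of the 42 fell at least 2-fold. Their median log2 fold change was -0.66, and 80 of the 100 had a value below 0. Among the 10 most abundant, 5 were called lower and 0 higher, with log2 fold changes from -2.25 to 0.05. With library size in place of TMM, 33 of the 100 were lower and 10 higher. With limma on log2(FPKM + 1), 1 was lower at an adjusted p under 0.05, and 44 at an unadjusted p under 0.05. The count called lower was 14 without full sunlight replicate 3, 18 without low light replicate 1, 24 without low light replicate 2 and 24 without low light replicate 3. It was 56 without full sunlight replicate 2, the library nearest to low light.

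A few genes were read in one condition alone. At least 5 counts in every full sunlight library and 0 in every low light library were found for 27 genes, and the reverse for 12. The other 9 ways of dividing the 6 libraries into 3 and 3, each of which mixes both conditions, gave at most 4 such genes. A gene read in one condition alone cannot qualify in a mixed division. These divisions therefore do not show how many such genes would arise without a difference between conditions. These genes were weakly expressed: the highest mean count was 27.7 among the 27 and 35.7 among the 12. The filter on low counts left 10 of the 39 in the test, and edgeR called all 10. These genes were picked on the same counts, so their calls are no separate support. A count of 0 in a library allows up to 3 counts, so a low level in the other condition was not detectable at this depth.

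The 2 named genes that rose most were TRINITY_DN29763_c0_g1 and TRINITY_DN19457_c0_g1. TRINITY_DN29763_c0_g1 stood at 47.3 ± 45.8 CPM (SD, n = 3) in full sunlight and 2.96 ± 2.39 in low light, a log2 fold change of 3.99 (SE 0.79, edgeR adjusted p = 0.0093). Its level was 97.9 CPM in full sunlight replicate 1, 35.5 in replicate 3 and 8.55 in replicate 2. Its log2 fold change was 2.89 without full sunlight replicate 1 and 4.88 without low light replicate 3. Without low light replicate 1 it was 3.69, and the call ended, with an edgeR adjusted p of 0.051. TRINITY_DN19457_c0_g1 stood at 21.5 ± 11.1 CPM in full sunlight and 1.64 ± 0.415 in low light. Its log2 fold change was 3.70 (SE 0.44, edgeR adjusted p = 0.0013), a 13.0-fold difference of the fitted levels, and the lowest full sunlight value was again that of replicate 2, at 8.79 CPM.

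The 2 named genes that fell most were TRINITY_DN2969_c0_g2 and TRINITY_DN15158_c0_g5. TRINITY_DN2969_c0_g2 stood at 1.52 ± 0.700 CPM (SD, n = 3) in full sunlight and 51.0 ± 45.7 in low light, a log2 fold change of -5.06 (SE 0.65, edgeR adjusted p = 0.0018). Low light replicate 1 reached 103 CPM against 18.4 and 31.4 in replicates 2 and 3, and without it the log2 fold change was -4.04. TRINITY_DN15158_c0_g5 stood at 1.36 ± 0.751 CPM in full sunlight and 31.4 ± 20.7 in low light. Its log2 fold change was -4.53 (SE 0.65, edgeR adjusted p = 0.0026). Low light replicate 1 was the lowest of its condition for this gene, at 7.48 CPM against 43.9 and 42.7. With limma on log2(FPKM + 1), the call of TRINITY_DN19457_c0_g1 held, with a log2 fold change of 3.12 (adjusted p = 0.049). Those of the other 3 genes ended: the log2 fold change was 3.22 for TRINITY_DN29763_c0_g1 (limma adjusted p = 0.127), -3.61 for TRINITY_DN2969_c0_g2 (0.0596) and -3.83 for TRINITY_DN15158_c0_g5 (0.0762). Fold changes on the log2(FPKM + 1) scale understate the change of genes with low values.

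**Figure D3:**
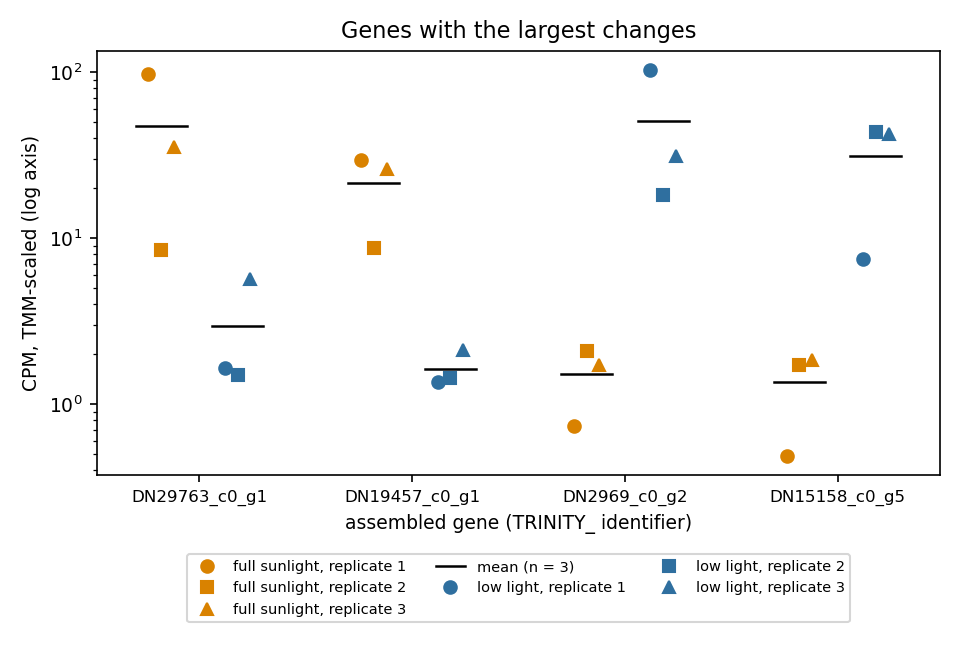
TMM-scaled CPM (log y axis) of the 4 named assembled genes (x axis), with 1 point per library and black lines for the mean of the 3 libraries of a condition. For TRINITY_DN29763_c0_g1 the full sunlight points run from 8.55 to 97.9 CPM, above the highest low light point at 5.72 CPM.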

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

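The genes called by edgeR (6173, of which 2714 were higher, 3459 lower and 42 among the lower of the 100 most abundant) stayed within 1.5 times of these counts with DESeq2 size factors, upper-quartile scaling, the DESeq2 test, limma-voom, no count filter and a strict count filter. With these settings 94.3% to 98.8% of the called genes were called again, and none of the shared calls changed direction. Without a count filter, the edgeR adjusted p of the 4 named genes was 5.6e-102 to 1.5e-43, against 0.0013 to 0.0093 in the main fit. Such values are hard to reconcile with the spread between their libraries, so the calls of that fit carry little weight. The cause was not tested. With library size alone 5187 genes were higher. Requiring a 2-fold change left 3319 genes (1319 higher, 2000 lower, 21 of the 100 most abundant lower), and an adjusted p under 0.01 left 1873 (727, 1146 and 13). With limma on log2(FPKM + 1) there were 894 calls (583, 311 and 1), with a pseudocount of 0.1 there were 1016 (723, 293 and 1), and without a filter 140 (106, 34 and 0). Of the 100 most abundant genes, 38 were lower at an unadjusted p under 0.05 in that last setting. The first FPKM setting shared 405 genes with the edgeR calls, 1 of them in the opposite direction, and the cause was not tested. Leaving out each library gave 2374 to 8976 calls, 933 to 3767 higher, 1432 to 5209 lower and 14 to 56 lower among the 100 most abundant. These fits have 5 libraries, so fewer calls are partly a matter of sample number; the exception was full sunlight replicate 2, whose omission gave more. The 4 named genes kept their direction in every fit. TRINITY_DN29763_c0_g1, TRINITY_DN2969_c0_g2 and TRINITY_DN15158_c0_g5 lost their calls in all 3 FPKM fits, TRINITY_DN19457_c0_g1 in 2 of them, and TRINITY_DN29763_c0_g1 also without low light replicate 1. The counts among the 100 most abundant genes, and the leaving out of libraries for the measures per library, were added after seeing the data. The differences in genes detected and in the share of the 100 most abundant genes kept their direction in each alternative, but 3 against 3 libraries cannot pass 0.05. The labels do not say that a replicate number marks a shared plant, day or batch, so the numbers were not taken as pairs. Libraries with the same replicate number also did not deviate together (correlations of 0.01, -0.04 and -0.03). The replicate block gave 4625 calls (1883 higher, 2742 lower). Set tests of gene lists (camera, fry, and the list alternatives) were not run, since the table pairs its identifiers with no names. Of the genes under 2 CPM, 6.45% were called. Depth may limit the calls there, but recovery by abundance was not tested.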

Other observations

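The 100 most abundant genes were singled out after the data had been seen. Of the tests below, the divisions of the libraries, the share of the 10 most abundant genes, the component test, the sizes of the length shifts and the level of genes nearly absent from full sunlight were chosen after the results they measure, or related ones, had been seen.

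Genes that the assembler placed in one component, a group of entries joined by shared sequence, tended to move together. Of 354 components with at least 2 called genes, 278 had all their called genes higher or all lower in full sunlight, and 76 had called genes in both directions. Permuting the directions 10000 times gave a median of 177 one-direction components and at most 210. Directions independent within a component are thus argued against. Entries of one component may be fragments or copies of one gene with reads split among them. The 278 therefore do not show that separate genes respond together. The 76 components with both directions, which may hold gene copies or fragments with different light responses, are not explained by that result of 278.

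The 6173 calls came from the true division of the libraries. The other 9 divisions into 3 and 3 gave at most 0 edgeR calls, with 456 to 2244 genes at an unadjusted p under 0.05. Likewise 42 of the 100 most abundant genes were called lower, and the other divisions called at most 0 in one direction, with at most 8 at an unadjusted p under 0.05. In each case the true division was the 1 of 10 with as many calls, and 10 divisions are too few for a share under 0.05. Each other division also mixes both conditions within its groups. A difference between the conditions then adds to the spread within groups and lowers the calls. The other divisions therefore do not show how many calls would arise without such a difference.

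The fall of the most abundant genes in full sunlight was weighed against TMM scaling and against displacement by the 10 most abundant genes. With library size alone, 33 of the 100 were called lower and 10 higher, which argues against the scaling as the cause for these 100, though not for the balance of calls under 200 CPM. Displacement of the others by the 10 most abundant genes would need these 10 to hold more of the counts in full sunlight. Their share was lower there in all 3 libraries, with a difference of means of -3.18 percentage points. These 10 belong to the 100, and their lower share had already been seen, so this outcome was known when the test was chosen. It says nothing about displacement by other genes. Light condition remains as an untested explanation, as do displacement by other genes and differences in harvest or batch, which the labels do not give.

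Full sunlight replicate 2 lay between the other full sunlight libraries and low light. A low light library under a full sunlight label is argued against. Genes were chosen by a 4-fold difference between full sunlight replicate 1 and low light replicates 1 and 2. On a scale from 0 (low light replicate 3) to 1 (full sunlight replicate 3), replicate 2 had a median position of 0.688 (95% bootstrap interval 0.662 to 0.712, 326 genes) over genes lower in full sunlight and 0.658 (0.543 to 0.731, 43 genes) over genes higher. Low light RNA mixed into replicate 2 needs one position for both, and the medians differed by -0.0305 (interval -0.151 to 0.0471), so a mixture with about 31.2% low light RNA stays open. Against it, 29 genes nearly absent from full sunlight replicates 1 and 3 stood in replicate 2 at a median 19.5% of their low light level (9.48% to 28.9%), though this interval meets that of the needed share (28.8% to 33.8%). The SD of the log2 ratio of replicate 2 to a mixture was 0.41 with 0% low light. It was lowest, at 0.302, with 35%, among shares up to 60%. Any library lying between the conditions may give such a fall, so it does not tell a mixture from other causes. A plant or leaf that received less light may give the same positions, and was not tested, since the labels give no plant, leaf position or light reading.

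The ratio of count to FPKM gives an effective length for each gene and library, and a shift in it between conditions may mark a change in which transcript forms are used. Among 20422 genes with at least 50 counts in every library, limma called 1961 lengths different (adjusted p under 0.05), 1715 longer and 246 shorter in full sunlight, with a median absolute log2 change of 0.09. The other divisions gave at most 2, the true one being 1 of 10, too few for a share under 0.05. Each of them mixes both conditions, so a difference between conditions widens its spread and lowers its calls. Rounding of low counts is argued against, since 10.02% were called among genes with at least 200 counts in every library and 9.60% among all. Removing each library's trend with length, as a difference in fragment length would produce, left 45 calls. A prediction written beforehand took such a small remainder as the outcome if fragment length was the cause, and it was met. The median shift of the 1961 genes, in its original direction, went from 0.09 (median SE 0.013) to 0.026 (median SE 0.0077) on the log2 scale, and 1046 of them kept an unadjusted p under 0.05. The trend thus covers much of the typical shift. Whether it covers all of it was not settled, since the genes were picked on the same libraries and without any 1 library the uncorrected calls were 0 to 6 (4498 to 5347 at an unadjusted p under 0.05). Genes with a called length were called by count in 24.02% of cases and the others in 19.24% (odds ratio 1.33, 95% interval 1.19 to 1.48, Fisher's exact test, two-sided p = 8.1e-07, genes taken as independent). Both kinds of call rest on the same counts, and abundance was not held equal in this comparison. The overlap therefore does not link length to expression. A change in transcript forms was not tested: it would need counts per transcript, which were not used here.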
